A study of Mus musculus with 18 samples.

How the data were processed

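ATAC-seq, in which Tn5 transposase cuts accessible DNA and leaves sequencing adapters in it, was measured in nuclei from the central amygdala (CeA) and the prefrontal cortex of C57BL/6J mice aged 2 to 3 months. The 18 libraries fall into 8 groups. SOM+ nuclei were gated on a nuclear GFP carried by somatostatin cells, and came from CeA and cortex of control and fear-conditioned mice, 2 libraries per group. Bulk nuclei were gated on a DNA stain alone, and came from CeA and cortex of mice with an Erbb4 knockout (KO) in SOM+ cells, 3 libraries per region, and of wild-type (WT) mice, 2 libraries per region. Each library held 50000 nuclei, and the protocol speaks of technical replicates when it describes the sort, so replicate libraries may not all be separate mice. The genotype field carries the KO entry for the WT libraries too, so WT was taken from the sample titles.

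The deposited values were counts: raw reads per promoter window, 1 kb to either side of a transcription start site, in the mouse build mm9, with 1 column per library and no normalization by the authors (all values were whole numbers and the column totals differed). Per the submitters' processing notes, the tools were bcl2fastq 2.16.0.10, Trimmomatic 0.32, Bowtie2, Picard 1.88 and MACS2. The program that counted the reads, its treatment of the Tn5 offset, of strand and of duplicates are not given in the sources used here. Promoter windows alone were deposited, so a total below is the promoter count of a library and not its sequencing depth, and neither peaks outside promoters nor the fragment lengths could be examined. Of 26728 entries, 663 repeated the window of another entry and were left out, which left 26065 windows. Of these, 24630 spanned 2000 bases and 1435 were wider, up to 6222 bases. Neighbouring windows can overlap and then share reads. In all, 354 windows had 0 counts in every library, and 95.4% of the gene names were in the reference gene table.

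Counts were tested with edgeR 4.0.16 in R 4.3.3 by quasi-likelihood F tests, with TMM scaling and with promoters kept by filterByExpr by group (minimum count 10, minimum total 15). P values were adjusted by the Benjamini-Hochberg method within each comparison, and a promoter is written as called at an adjusted p under 0.05. The fits numbered 3, over the 8 SOM+ libraries (25157 promoters, 4 residual degrees of freedom), the 10 bulk libraries (25196 promoters, 5 residual degrees of freedom) and all 18 libraries (25246 promoters, 9 residual degrees of freedom). The last 2 held the labelled sex as a term. There were 11 comparisons: fear conditioning in each region, averaged over regions and as an interaction with region; Erbb4 KO in the same 4 ways; CeA against cortex in SOM+ and in bulk nuclei; and SOM+ control against bulk WT. Differences are log2 fold changes with their standard error (SE), levels are TMM-scaled CPM (each count over the scaled library total, times 1e+06) as mean ± standard deviation (SD), and list tests used log2 CPM with a prior count of 2. The adjusted p values measure the spread between samples and no other source of error.

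Lists of genes fixed in advance numbered 22: GABAergic neuron, somatostatin neuron, other interneuron, glutamatergic neuron, CeA and striatal type neuron, pallial and cortical regional, astrocyte, oligodendrocyte, microglia, vascular, immediate early, synaptic plasticity, GABA and neuropeptide receptor, glucocorticoid and stress, chromatin modifier, ErbB and neuregulin signalling, Y linked, cytosolic ribosomal protein, olfactory receptor, OXPHOS subunit, clustered protocadherin and Hox. Some genes stand in more than 1 list. Where a gene had several windows, the one with the highest mean count stood for it. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes and again with an estimated correlation, adjusted over the lists of a comparison, and members called were counted both over all promoters and adjusted over the list alone. Genes named in the text followed a rule fixed in advance: up to 8 promoters per direction with the smallest p among those called whose values did not overlap between the groups, predicted genes and receptor or small RNA clusters left out; where fewer than 3 were called, the 3 with the smallest p; Erbb4 and Sst always; and 2 to 4 members of each list discussed. A statement on the smallest p covers the promoters this rule leaves in. A name outside this rule is said to have been chosen after its values were seen.

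Promoter enrichment was taken per library as the median CPM of cytosolic ribosomal protein promoters, open in every cell type, over that of olfactory receptor promoters, closed in brain. Groups were compared by exact two-sided permutation tests. Counts of 0 allow up to 3 counts, a limit that covers counting error only and is given in CPM of the library total without TMM scaling. The fits were tested on simulated data made from the counts, with 100 promoters changed at each fold. A 2-fold change was recovered in 52.0% of them for fear conditioning in CeA, 75% for its average over regions, 60% for the average effect of KO and 71% for CeA against cortex in SOM+ nuclei. At 1.5-fold these shares were 6.06%, 30.6%, 6.06% and 44.4%. False calls were 1 of 58, 5 of 110, 1 of 67 and 9 of 124 calls, in the same order. The simulated counts varied independently between libraries and held no structure shared by samples. The shares may therefore be too high for the real libraries.

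Alternatives tried were DESeq2 1.42.0 with its own size factors, scaling by total count, limma-voom with cyclic loess scaling, no filter on low counts, autosomal promoters alone, leaving out each library in turn, the replicate number as a block, no sex term, and, for lists and enrichment, an estimated correlation and a ratio of means. Where a library left out leaves its group with 1 library, that library is assumed to vary like the other groups. Libraries of the same number resembled each other between some groups and not between others (correlation of their departures from the group mean from -0.386 to 0.412), and no label says that the numbers pair the libraries, so the number was used as a block in an alternative alone. CeA and cortex libraries of one number may still come from the same mice. The fits treat them as separate, so tests over both regions may rest on fewer mice than libraries. Sex as the Y-linked promoters show it, the fits without certain bulk libraries and the restriction to promoters of at least 10 CPM were added after the data were seen. Sites outside promoters, allele-specific signal and single-base footprints were left out because the counts do not hold them.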

Results

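Chromatin accessibility at promoters was measured by ATAC-seq in nuclei of the mouse central amygdala (CeA) and prefrontal cortex, in somatostatin-positive (SOM+) nuclei after fear conditioning and in bulk nuclei of mice that lacked Erbb4 in SOM+ cells. The CeA drives learned defensive responses, and Erbb4 is the receptor through which neuregulins act on interneurons. Control and fear-conditioned SOM+ nuclei were represented by 2 libraries per region, the first of each pair labelled male and the second female. Bulk nuclei were represented by 3 Erbb4 knockout (KO) libraries per region, all labelled male, and by 2 wild-type (WT) libraries, the first labelled female and the second male. Promoter counts per library ranged from 2648959 to 7727263 in CeA SOM+, from 9452310 to 14668694 in cortex SOM+, from 2751769 to 7220446 in CeA bulk and from 5146020 to 7939962 in cortex bulk nuclei. A count of 0 therefore allows a level of up to 0.205 CPM in the deepest library and up to 1.13 CPM in the shallowest, both without TMM scaling.

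Housekeeping promoters stood out from closed ones most in cortex SOM+ nuclei. The median level of cytosolic ribosomal protein promoters over that of olfactory receptor promoters was 64.5 ± 13.4 in cortex SOM+ control (SD, n = 2) and 57.8 ± 4.87 in cortex SOM+ fear (n = 2). It was 29.5 ± 6.86 in CeA SOM+ control and 26.6 ± 12.6 in CeA SOM+ fear (n = 2 each). In bulk nuclei it was 18.0 ± 1.41 in CeA KO (n = 3), 13.1 ± 3.80 in CeA WT (n = 2), 12.5 ± 2.45 in cortex KO (n = 3) and 11.5 ± 2.38 in cortex WT (n = 2). SOM+ nuclei of the CeA were lower in this ratio than those of the cortex, 28.0 ± 8.45 against 61.1 ± 9.11 (n = 4 each, exact permutation p = 0.0286, the smallest that 70 arrangements allow). SOM+ control nuclei were higher than bulk WT nuclei, 47.0 ± 22.0 against 12.3 ± 2.75 (n = 4 each, exact permutation p = 0.0286). Fear-conditioned and control libraries did not differ detectably (42.2 ± 19.6 against 47.0 ± 22.0, exact permutation p = 0.743). Neither did KO and WT libraries (15.3 ± 3.47, n = 6, against 12.3 ± 2.75, n = 4, exact permutation p = 0.195) or bulk CeA and bulk cortex (16 ± 3.42 against 12.1 ± 2.18, n = 5 each, exact permutation p = 0.0714). The tests of fear conditioning, of KO and of SOM+ against bulk pooled CeA and cortex, and their arrangements ignored region. The region difference is part of those SDs, so the fear test could hardly detect a difference. Libraries of one group correlated across promoters at r = 0.951 to 0.984, where promoters are not independent replicates, and libraries of different groups at r = 0.785 to 0.986. Fear and control libraries of cortex with the same number were closer than those of one group, with r = 0.985 for the second of each. Libraries of one group differed by more than counting error, with a chi-squared of at least 3.26 per degree of freedom.

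**Figure D1:**
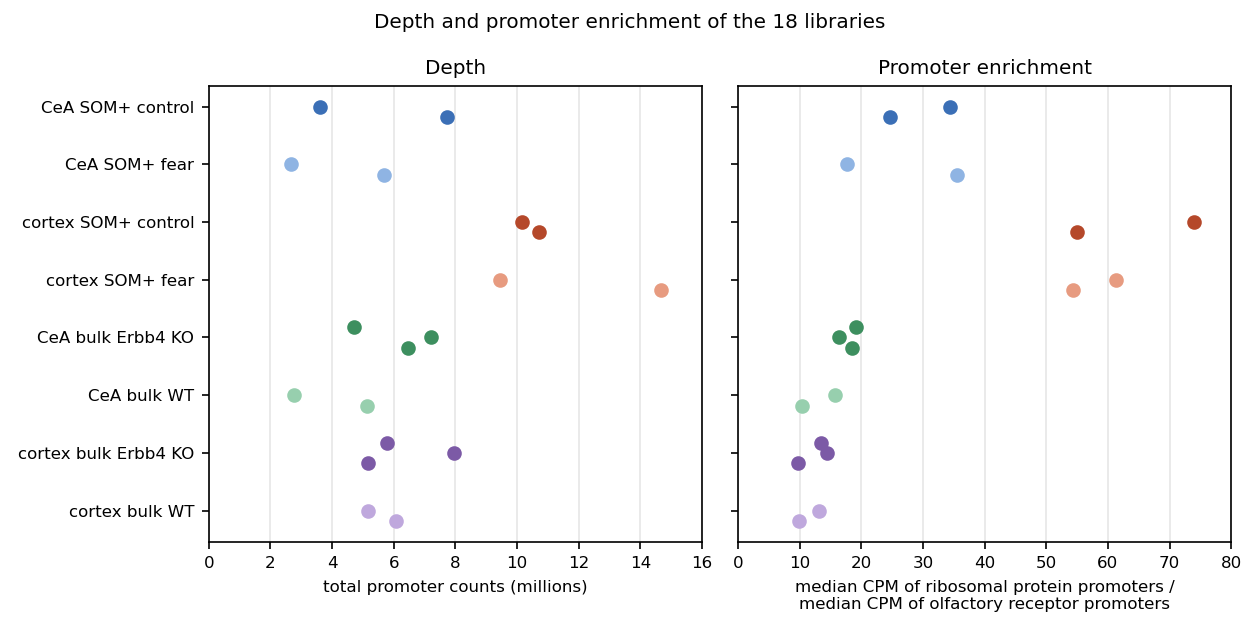
Each point is 1 library, in the line of its group, with its total promoter counts in the left panel and the ratio of the median CPM of ribosomal protein promoters to that of olfactory receptor promoters in the right panel. The 4 cortex SOM+ libraries had the highest ratios and the largest totals.

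SOM+ control nuclei were compared with bulk WT nuclei, 4 libraries each, to see which promoters the sort for somatostatin cells selected. Gad1, which encodes a GABA-synthesizing enzyme, was higher in SOM+ nuclei by 1.51 ± 0.15 log2 (SE), at 90.2 ± 6.40 CPM in SOM+ against 35.5 ± 19.3 CPM in bulk (SD, n = 4 each, adjusted p = 6.75e-11; chromosome 2, 70399186 to 70401185 in mm9), with each SOM+ library above each bulk one. The vesicular GABA transporter Slc32a1 (1.62) and the interneuron transcription factors Dlx1 (1.41) and Dlx2 (1.48) rose with it. Clustered protocadherins, adhesion molecules that give each neuron a surface identity, were higher at all 58 measured promoters, led by Pcdhb6 (3.22 log2, 34.3 against 3.77 CPM) and Pcdha4 (2.45). Promoters that were lower included Ermn (-2.63) and Ugt8a (-2.57) of oligodendrocytes, Gja1 (-2.19) and Slc4a4 (-1.81) of astrocytes, and Neurod1 (-2.27) and Bhlhe22 (-2.08), transcription factors of glutamatergic neurons. Erbb4 was itself lower in SOM+ nuclei, by 0.92 ± 0.17 on the log2 scale (20.4 against 38.0 CPM, adjusted p = 1.18e-05). Sst, the somatostatin gene, did not differ (0.03 ± 0.23, adjusted p = 0.926).

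Of 25246 promoters tested, 15437 were called, 7718 higher in SOM+ nuclei and 7719 lower, of which 2917 and 4378 differed by more than 2-fold. DESeq2 called 15538 and limma with cyclic loess scaling 14319. By the naming rule, the promoters with the smallest p among those higher were Tmem87a (1.96), Ganc, whose window overlaps it and shares its reads (1.94), Cep250 (2.03), Pla2g4e, Zfp759 (2.04), Zfp566 (1.95), Dhrs13 (1.97) and Fahd1 (1.92). Those lower were Nfib, a transcription factor of glial and neuronal progenitors (-2.36 ± 0.16; 15.7 ± 5.00 against 80.4 ± 24.1 CPM, SD, n = 4 each, adjusted p = 1.42e-13; chromosome 4, 82150684 to 82152683), Aga (-2.69), Hpgd (-3.06), Tnc (-2.53), Cnksr3 (-2.32), the noncoding RNA Pnky (-2.30) and Jam2 (-2.27). The called promoters that were higher had a median of 50.4 CPM and those lower 11.9 CPM. Scaling by total count moved the median of all promoters to -0.27 log2 and the share of calls that were higher from 50.0% to 39.0%. Sort, mouse line and preparation differ together between these groups, so their parts in a difference cannot be separated.

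Over all promoters, 13 of 19 GABAergic neuron promoters were higher and 3 lower in SOM+ nuclei (median 0.76, adjusted p = 0.00622). The somatostatin neuron list was divided, with 6 of 23 higher and 7 lower (median -0.21, adjusted p = 0.823). Prodynorphin Pdyn (1.27) rose and the neurokinin receptor Tacr1 (-1.45) fell. Cortistatin Cort was higher by 1.59 on average, but in cortex alone (94.9 against 9.85 CPM) and not in CeA (14.1 against 14.9 CPM, n = 2 each). Markers of other interneurons had 2 of 20 higher and 9 lower (median -0.43, adjusted p = 0.111), as Adarb2 (-2.09) and Ndnf (-1.72) fell and Cplx1 (1.29) rose. Glutamatergic neuron promoters were lower in 19 of 30 and higher in 5 (median -0.70, adjusted p = 0.00434). CeA and striatal type markers were lower in 12 of 32 and higher in 7 (median -0.13, adjusted p = 0.379). Among these, Foxp2 (-1.99) and the receptor gene Calcrl (-2.11) fell. Pallial and cortical regional genes were lower in 16 of 26 and higher in 3 (median -0.76, adjusted p = 0.00386). Adjusted over each list alone these counts were the same, save that 4 pallial genes were higher. With an estimated correlation, adjusted p was 0.257 for GABAergic, 0.188 for glutamatergic and 0.257 for pallial genes.

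Astrocyte promoters were lower in 14 of 20 and higher in 2 (median -0.99, adjusted p = 0.00168). Oligodendrocyte promoters were lower in 14 of 25 with 0 higher (median -0.82, adjusted p = 0.00175). Microglia promoters, such as Ptprc (-1.83), the leukocyte surface phosphatase CD45, were lower in 9 of 22 and higher in 1 (median -0.47, adjusted p = 0.0184). Vascular promoters, such as Kdr (-1.32), a receptor for VEGF, were lower in 17 of 29 and higher in 3 (median -0.59, adjusted p = 0.00443). Receptors for GABA and neuropeptides were lower in 22 of 37 and higher in 3 (median -0.64, adjusted p = 0.00123), including the neuropeptide Y receptors Npy1r (-1.72) and Npy5r (-1.86). Adjusted over each list alone these counts were the same, save that 13 oligodendrocyte promoters were lower. With an estimated correlation, adjusted p was 0.188 for astrocyte and oligodendrocyte, 0.400 for microglia, 0.190 for vascular and 0.267 for receptor genes. SOM+ nuclei had the higher promoter enrichment. Of all 3551 promoters under 10 CPM called lower in them, 36.9% were called lower again under cyclic loess. At weak promoters of these lists, a lower value may therefore come in part from enrichment and not from fewer such cells.

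Synaptic plasticity promoters were higher in 20 of 45 and lower in 6 (median 0.36, adjusted p = 0.0306), although Bdnf, which encodes a neurotrophin, fell by 1.92 on the log2 scale. Immediate early promoters were higher in 17 of 36 and lower in 11 (adjusted p = 0.196), with a median of 0.23 that turned to -0.09 under cyclic loess. The activity-dependent factor Npas4 was higher by 1.75. Chromatin modifiers were higher in 29 of 53 and lower in 7 (median 0.41, adjusted p = 0.00266), among them Suz12 of Polycomb complex PRC2 (1.5) and the acetyltransferase Kat5 (1.51). ErbB and neuregulin signalling promoters were higher in 22 of 48 and lower in 9 (median 0.35, adjusted p = 0.0481). The ligand gene Nrg2 rose by 1.54 and the ligand gene Btc fell by 2.13. Glucocorticoid and stress promoters were higher in 10 of 28 and lower in 9 (adjusted p = 0.823), with a median of 0.03 that turned to -0.17 with total count scaling and -0.19 under cyclic loess. Adjusted over each list alone these counts were the same, save that 30 chromatin modifiers were higher. Camera with an estimated correlation gave adjusted p = 0.400 for plasticity, 0.257 for chromatin and 0.267 for ErbB genes.

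Enrichment, higher in SOM+ nuclei, is the ratio of ribosomal protein to olfactory receptor promoters, so the differences of these lists restate it. Cytosolic ribosomal protein promoters were higher in 49 of 82 and lower in 14 (median 0.55, adjusted p = 0.000399), and OXPHOS subunit promoters in 40 of 88 with 16 lower (median 0.28, adjusted p = 0.00618). Olfactory receptor promoters were lower in 657 of 1096 and higher in 2 (656 and 1 adjusted over the list alone, adjusted p = 1.01e-15), and their median of -1.22 became -0.29 under cyclic loess. Hox promoters were lower in 15 of 39 with 0 higher (11 and 0 adjusted over the list alone, median -0.62, adjusted p = 0.00356). All 58 protocadherin promoters were also higher under cyclic loess, where the median went from 1.93 to 2.23 (adjusted p = 4.83e-19). Adjusted over the list alone, ribosomal protein, OXPHOS and protocadherin counts were the same. With an estimated correlation, adjusted p was 0.257 for ribosomal protein and olfactory receptor, 0.403 for OXPHOS, 0.5 for Hox and 0.188 for protocadherin promoters. Of 5 Y-linked promoters, 1 was lower, Eif2s3y (-2.01, adjusted p = 0.0409), a gene chosen after its value was seen. Adjusted over the list alone 0 passed, as under cyclic loess, where the list's median went from -1.69 to 0.70 (adjusted p = 0.379 for the list by camera). The call of Eif2s3y ended without CeA control 2, cortex control 2, CeA WT 1 or cortex WT 1 (adjusted p up to 0.202). It was also lost without the sex term (-0.57), and the sign turned under cyclic loess (0.30) and with sex taken from the Y-linked promoters (0.37).

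**Figure D2:**
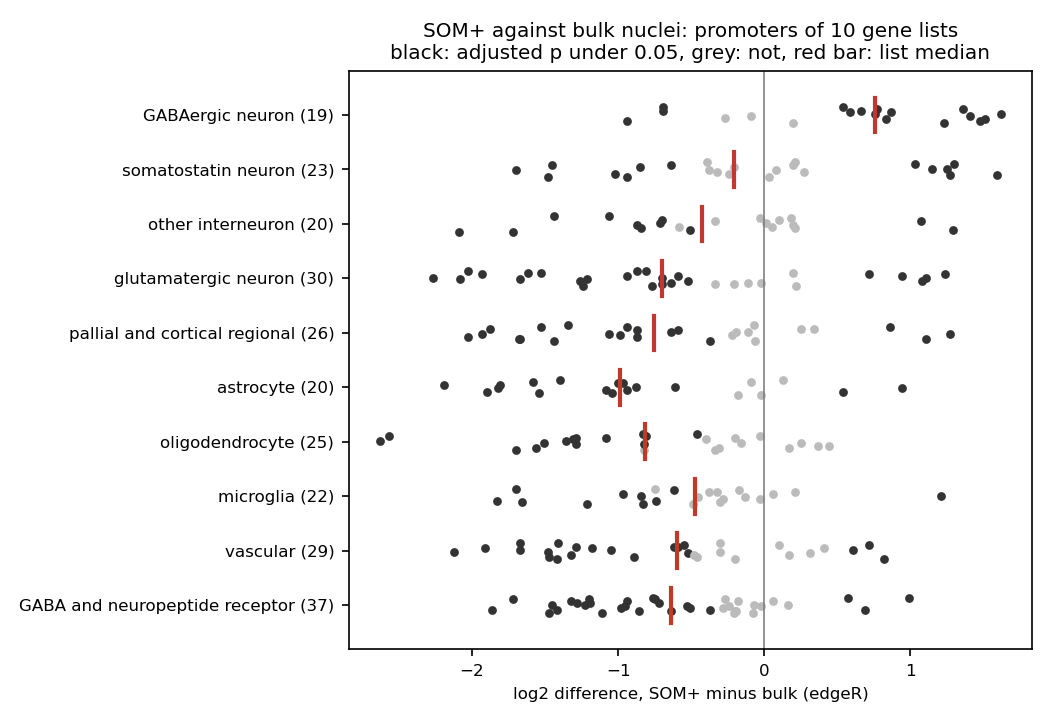
Log2 difference of each measured promoter between SOM+ control and bulk WT nuclei in 10 lists; black points were called, grey points were not, and the red bar is the median of the list. GABAergic neuron promoters lay mostly above 0, and astrocyte, oligodendrocyte and glutamatergic neuron promoters mostly below.

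SOM+ nuclei of the CeA and of the cortex were compared, 4 libraries each, for what sets somatostatin cells of the 2 regions apart. In CeA SOM+ nuclei the enkephalin gene Penk was higher by 2.51 ± 0.17 log2 (42.6 ± 5.58 against 7.56 ± 2.12 CPM, SD, n = 4 each, adjusted p = 1.23e-43; chromosome 4, 4064593 to 4066592), as were Meis2 (1.73), Zfhx3 (2.02) and Ebf1 (1.94), transcription factors of striatal and amygdalar neurons. Cortistatin Cort, made by cortical somatostatin interneurons, was lower by 2.77 ± 0.17 in CeA (13.3 ± 1.9 against 93.6 ± 6.54 CPM, n = 4 each, adjusted p = 3.08e-58; chromosome 4, 148499873 to 148501872). The interneuron transcription factor Lhx6 (-2.10; 22.2 against 96.8 CPM), Maf (-2.12) and Sox6 at 1 of its start sites (-1.93) were lower as well. Among genes the naming rule covers, which leaves out predicted ones, the smallest p was at Slco5a1, an organic anion transporter family member (3.02 ± 0.16; 110 ± 8.94 against 13.8 ± 1.66 CPM, adjusted p = 9.02e-75; chromosome 1, 12980217 to 12982216), and Spink8 was higher by 3.37 (50.5 against 4.91 CPM).

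Of 25157 promoters, 12143 were called, 5314 higher in CeA and 6829 lower, of which 2369 and 1422 differed by more than 2-fold. DESeq2 called 11251 and limma with cyclic loess 10697. Beside Slco5a1 and Spink8, the promoters named by rule that were higher were Ptprd (2.89; 147 against 20.3 CPM), Zfhx4 (2.99), Pifo (2.65), Retn (3.34), P2ry1, an ADP receptor (2.60), and Dcun1d1 (2.47). Those lower beside Cort were Col19a1 (-2.98; 6.71 against 54.6 CPM), the zinc transporter Slc30a3 (-2.60), Ntn4 (-2.52), the delta opioid receptor Oprd1 (-2.43), Dlx1as (-2.45), Tmem229b (-2.48) and Nupr1 (-2.67). Scaling by total count moved the median of all promoters from 0.04 to 0.26 and turned the share of calls higher in CeA from 43.8% to 61.5%. Under cyclic loess that share was 50.3%. The called promoters that were higher had a median of 13.2 CPM and those lower 46.0 CPM, and the CeA libraries had the lower enrichment.

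CeA and striatal type genes were higher in CeA SOM+ nuclei at 19 of 32 promoters and lower at 4 (median 0.58, 0.73 under cyclic loess, adjusted p = 0.000431). Somatostatin neuron markers were lower at 13 of 23 and higher at 5 (median -0.79, adjusted p = 0.0099), among them Crhbp, which binds corticotropin-releasing hormone (-1.88). GABAergic neuron genes were divided, 6 of 19 higher and 9 lower (adjusted p = 0.195), with Sp8 (2.32) up and Dlx1 (-1.94) down. Their median of -0.21 was 0.00 with total count scaling. Receptors for GABA and neuropeptides were higher at 17 of 37 and lower at 7 (median 0.33, adjusted p = 0.0454). The serotonin receptor Htr2c (2.44) and the GABA receptor subunit Gabra5 (1.28) led them, while the serotonin receptor Htr2a fell by 1.60. Glucocorticoid and stress genes were lower at 11 of 28 and higher at 3 (median -0.37, adjusted p = 0.0163), such as the glucocorticoid receptor cochaperone Fkbp5 (-1.08) and the phosphatase Dusp1 (-0.91). Chromatin modifiers were lower at 27 of 53 and higher at 8 (median -0.35, adjusted p = 0.0163), with the deacetylase Hdac1 (-1.88) and the acetyltransferase Ep300 (-1.25) in front. Under cyclic loess 16 were higher and 13 lower. Adjusted over each list alone these counts were the same, save that 28 chromatin modifiers were lower. With an estimated correlation, adjusted p was 0.792 for somatostatin and stress genes and 0.793 for CeA type, receptor and chromatin genes.

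Clustered protocadherins were higher in CeA SOM+ nuclei at 28 of 58 promoters and lower at 6 (29 and 6 adjusted over the list alone, median 0.40, adjusted p = 0.00268). Pcdhb1 was at 2.09 and Pcdhgb4 at 1.23. Hox promoters were higher at 11 of 39 (7 adjusted over the list alone, adjusted p = 0.00215), with a median of 0.47 that shrank to 0.06 under cyclic loess. Olfactory receptors were higher at 312 of 1084 and lower at 3 (206 and 2 adjusted over the list alone, adjusted p = 5.37e-15). Their median of 0.89 turned to -0.08 under cyclic loess, and Olfr452 was higher by 3.21 (39.2 against 4.39 CPM). Each of these 3 lists had adjusted p = 0.793 with an estimated correlation. Medians near 0 changed sign with scaling for ribosomal protein (-0.21, 0.04 under cyclic loess), OXPHOS subunit (-0.16, 0.05), oligodendrocyte (0.22, -0.04), ErbB and neuregulin (-0.18, 0.04 with total count scaling), other interneuron (-0.16, 0.06) and pallial (-0.11, 0.10) promoters. Erbb4 was lower in CeA SOM+ nuclei by 0.41 ± 0.17 (19.1 ± 3.06 against 25.8 ± 1.67 CPM, n = 4 each, adjusted p = 0.0364). That call ended without any 1 of the 8 libraries (adjusted p up to 0.171), as well as with DESeq2, with total count scaling and under cyclic loess (adjusted p = 0.235 for the last). Sst did not pass (0.23 ± 0.18, adjusted p = 0.295). It was called without the library labelled CeA control 2, and over the 8 libraries left out in turn it ran from -0.12 to 0.52, with its sign changed once.

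Bulk nuclei of CeA and cortex were compared, 5 libraries each, for the regional difference over all cells. Dlx6, a homeobox factor of GABAergic neurons, was higher in CeA by 1.94 ± 0.14 log2 (106 ± 20.2 against 27.3 ± 3.97 CPM, SD, n = 5 each, adjusted p = 1.37e-08; chromosome 6, 6812334 to 6814333). Slc32a1 (1.85), Dlx5 (1.59) and the GABA-synthesizing Gad2 (1.5) followed. Neurod6, a factor of pyramidal neurons, was lower in CeA at -2.76 ± 0.17 (11.6 ± 4.04 against 81.0 ± 13.8 CPM, n = 5 each, adjusted p = 1.75e-09; chromosome 6, 55630258 to 55632257). Tbr1 (-1.66), Emx1 (-1.5) and Bdnf (-1.95) were lower too. The striatal phosphatase inhibitor Ppp1r1b (1.46) and Penk (0.98) were higher in CeA. Erbb4 did not differ (-0.05 ± 0.15, adjusted p = 0.844).

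Of 25196 promoters, 4253 were called, 1739 higher in CeA and 2514 lower, of which 187 and 423 differed by more than 2-fold. DESeq2 called 4308 and limma with cyclic loess 4369. Others named by rule were Ddc, the enzyme that makes dopamine and serotonin from their precursors (2.31), the GABAergic factor Sp9 (1.96), the striatal factor Six3 (2.35) and Izumo1r (1.77) among those higher. Those lower were Nrn1 (-2.07), Osbpl1a (-2.27), Mgp (-2.08), Fap (-2.14), Figf (-2.45), Sprr2g (-2.04) and Bhlhe22 (-1.64). Scaling by total count moved the median of all promoters from 0.03 to 0.13 and the share of calls higher in CeA from 40.9% to 56.7%. With autosomal promoters alone, scaled among themselves, that share was 30.8%. The count rested on single libraries: it was 2726 without CeA KO 2, 2691 without CeA KO 3, 1415 without CeA WT 1, 889 without CeA WT 2, 6991 without cortex KO 1, 1375 without cortex WT 1 and 895 without cortex WT 2. The cortex libraries KO 3 and WT 2 stood apart from the other bulk libraries on the first principal component (scores of -71.3 and -62.8, with the others between -9.5 and 57.9). Without both the count was 1974.

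GABAergic neuron promoters were higher in CeA bulk nuclei at 9 of 19 and lower at 1 (10 and 1 adjusted over the list alone, median 0.45, adjusted p = 8.86e-06). Glutamatergic neuron promoters were lower at 16 of 30 and higher at 2 (17 and 3 adjusted over the list alone, median -0.65, adjusted p = 2.02e-07). CeA and striatal type promoters were higher at 15 of 32 and lower at 1 (15 and 2 adjusted over the list alone, median 0.35, adjusted p = 2.42e-05). Pallial ones were lower at 13 of 26 and higher at 2 (13 and 4 adjusted over the list alone, median -0.39, adjusted p = 7.55e-05). Ribosomal protein promoters were higher at 14 of 82 and lower at 2 (15 and 2 adjusted over the list alone, median 0.15, adjusted p = 0.00852). Clustered protocadherins were higher at 7 of 58 (5 adjusted over the list alone, median 0.51, adjusted p = 1.48e-07). Of the 39 Hox promoters, 1 was called, Hoxd10 (0.68), named after its value was seen. Adjusted over the list alone 0 passed, and the list had a median of 0.45 (adjusted p = 0.000586). With an estimated correlation, adjusted p was 0.305 for glutamatergic, 0.345 for GABAergic, CeA type and pallial, 0.418 for ribosomal protein and protocadherin, and 0.697 for Hox promoters.

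Several of the smaller calls between bulk regions rested on single libraries. The Sst promoter was higher in CeA by 0.69 ± 0.21 (20 ± 4.64 against 12.6 ± 4.10 CPM, n = 5 each, adjusted p = 0.0293). That call ended without any 1 of CeA KO 1, CeA KO 2, CeA WT 1, CeA WT 2, cortex KO 2, cortex WT 1 and cortex WT 2 (adjusted p up to 0.32) and under cyclic loess (adjusted p = 0.0648). The call of Isl1, a factor of striatal and amygdalar neurons (0.87), ended without cortex WT 1 (adjusted p = 0.0532). That of Rpl19 (0.73) ended without CeA WT 2 or cortex WT 2 (adjusted p up to 0.0753), and that of Rpl27 (0.61) without CeA WT 2, cortex WT 1 or cortex WT 2 (adjusted p up to 0.0748). The calls of Pcdha6 (1.23) and Pcdhgb8 (0.79) ended without any 1 of the 4 WT libraries (adjusted p up to 0.111 and 0.233). The call of Hoxd10 was kept without cortex KO 1 and ended without any other 1 of the 10 bulk libraries (adjusted p up to 0.287), as well as under cyclic loess (adjusted p = 0.0927).

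The regional differences of SOM+ nuclei were not those of bulk nuclei. Across 25101 promoters, which are not independent replicates, the log2 differences in the SOM+ and bulk nuclei correlated at r = 0.008 (-0.06 over the 16359 promoters of at least 10 CPM, 0.06 over all under cyclic loess). Of 2412 promoters called in both, 1061 (44.0%) had the same sign. Promoters lower in CeA among SOM+ nuclei and higher in CeA among bulk nuclei numbered 818 where independence gives 473, those higher in both 398 against 367, those lower in both 663 against 684, and those higher in SOM+ and lower in bulk 533 against 531. Penk was higher in CeA in both kinds of nuclei, while Lhx6 and Cort were lower in CeA in SOM+ nuclei, the kind in which they mark cortical interneurons.

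**Figure D3:**
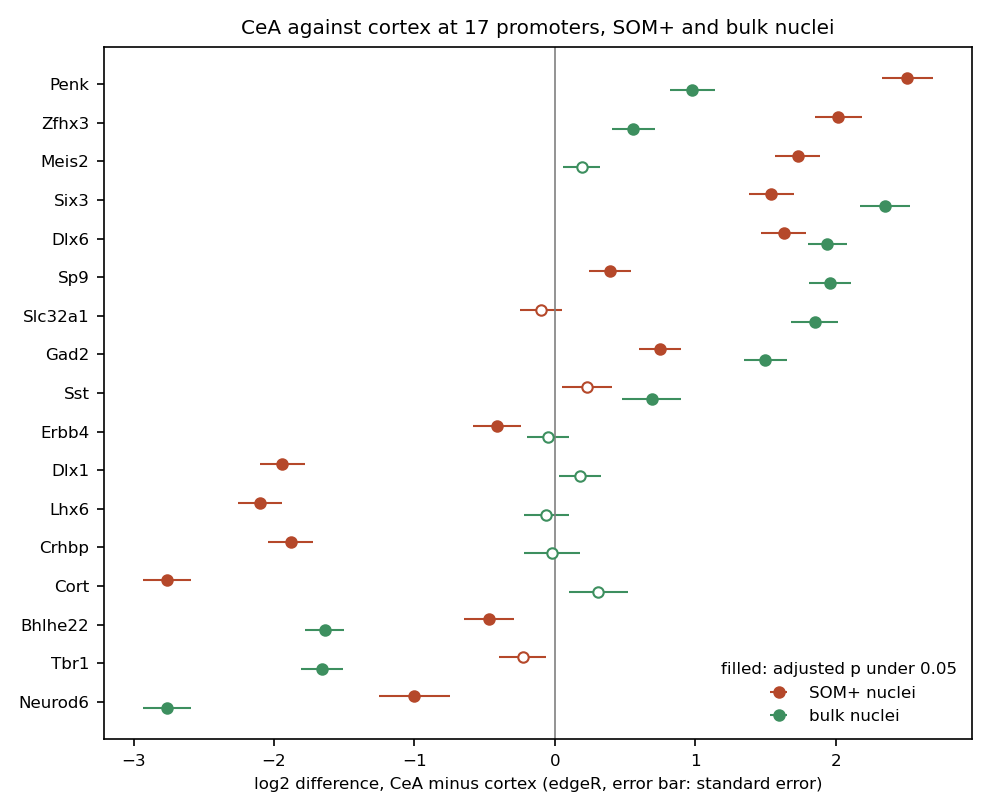
Log2 difference of CeA minus cortex for 17 named promoters in SOM+ and bulk nuclei, estimated with edgeR; bars are the SE and filled points had an adjusted p under 0.05. Penk was positive in both kinds of nuclei, and Neurod6 had its strongly negative value in bulk nuclei.

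Fear conditioning, which teaches mice to associate a cue with a shock, was tested in SOM+ nuclei of the CeA, 2 fear-conditioned against 2 control libraries. The promoter of Foxl2os, antisense to the forkhead gene Foxl2, was at 25.4 ± 0.678 CPM after fear conditioning and 11.8 ± 5.56 CPM in controls (SD, n = 2 each; 1.07 ± 0.26 log2, adjusted p = 0.935; chromosome 9, 98854730 to 98856729). That of Foxl2, which overlaps it and shares its reads, differed by 1.01. Fam57b, a regulator of ceramide synthesis, was at 11.1 ± 0.480 against 3.81 ± 0.431 CPM (1.54 ± 0.40, adjusted p = 0.935). Rhox6 had 0 counts in both fear libraries, which allows up to 0.529 and 1.13 CPM without TMM scaling, and 2.92 ± 1.21 CPM (TMM-scaled) in controls. Tsta3 (-0.76) and Insl3 (-1.30) were named by rule among those lower. None of these passed, as edgeR, DESeq2 and limma with cyclic loess each called 0 of 25157 promoters, and 598 (2.38%) had an unadjusted p under 0.05 by edgeR. Immediate early genes, the first that activity induces in neurons, had 0 of 36 members called (0 adjusted over the list alone, median -0.04), with Fos at -0.32, Npas4 at -0.29 and Maff at -0.45. The Fos value rested mostly on CeA fear 2 (50.8 CPM), as CeA fear 1 was at 76.6 CPM and the controls at 79.8 and 83.0 CPM. Without the library labelled CeA control 1, edgeR called Ddx3y, Eif2s3y, Uty and Foxl2os, genes chosen after their values were seen. The remaining CeA control library was labelled female and had 0 counts at the first 3, which are Y linked.

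In cortex SOM+ nuclei, the porphyrin synthesis gene Alad differed by 0.69 ± 0.20 log2 between 2 fear-conditioned and 2 control libraries (52.3 ± 10.9 against 33.0 ± 3.76 CPM, SD, n = 2 each, adjusted p = 1.00). Its neighbour Hdhd3 differed by 0.67 and Ddc by 1.09. Values were lower after fear conditioning at Ofcc1 (-2.06), the lymphocyte kinase gene Pik3cd (-0.79) and Rab34 (-0.55), none of them past the test. All of edgeR, DESeq2 and limma with cyclic loess called 0 promoters, and 288 (1.14%) had an unadjusted p under 0.05 by edgeR. Of the immediate early genes 0 were called (0 adjusted over the list alone, median -0.02), Fosb being at -0.30 and Maff at -0.20. Hox (median 0.23) and olfactory receptor promoters (median 0.10, but 0.009 under cyclic loess) were higher as lists by camera (adjusted p = 0.0314 each, and adjusted p = 0.982 with an estimated correlation), with 0 members called and 0 adjusted over the list alone. Without the library labelled cortex control 1 or that labelled cortex fear 1, the Y-linked Ddx3y, Eif2s3y and Uty, chosen after their values were seen, were called, as these were the male library of each group.

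Averaged over the regions, 4 fear-conditioned against 4 control libraries, Foxl2os was at 24.4 ± 2.14 against 15.8 ± 6.83 CPM (SD, n = 4 each; 0.65 ± 0.18 log2, adjusted p = 1.00). Foxl2 differed by 0.62 and the endothelial receptor gene Robo4 by 1.30. CeA and cortex libraries may come from the same mice, so 4 libraries a side may be fewer mice. Among those lower were Tsta3 (-0.54) and DQ267101 (-0.70) and AF357425 (-0.66), small RNA genes of the imprinted Dlk1-Dio3 domain. The plasticity list had 0 of 45 members called (0 adjusted over the list alone, median -0.05), with the NMDA receptor subunit Grin2a at -0.39. The serotonin receptor Htr2a was at -0.55. Erbb4 was at 24.4 ± 3.17 against 20.4 ± 4.63 CPM (0.29 ± 0.17, adjusted p = 1.00) and Sst at 17.6 ± 3.27 against 18.2 ± 6.28 CPM (-0.07 ± 0.18, adjusted p = 1.00). By edgeR, DESeq2 and limma with cyclic loess 0 promoters were called, and 530 (2.11%) had an unadjusted p under 0.05 by edgeR. Without CeA control 1, cortex control 1 or cortex fear 1, the Y-linked Ddx3y, Eif2s3y and Uty were called, in the average and in the test of the regions against each other alike.

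The difference between the regions in the response to fear conditioning also gave 0 calls by edgeR, DESeq2 and limma with cyclic loess, with 371 promoters (1.47%) at an unadjusted p under 0.05 by edgeR. Zp4-ps (1.40), Mxra8 (1.29) and Ihh (1.31) were named by rule with positive differences of CeA minus cortex response, and the chemokine Cxcl14 (-1.84), Dach1 (-1.27) and Cdh17 (-2.73) with negative ones, none past the test (adjusted p = 1.00 for each). Across the 16359 promoters of at least 10 CPM, which are not independent replicates, the responses of the regions correlated at r = 0.141.

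The Erbb4 KO was examined first at Erbb4 itself (chromosome 1, 69153634 to 69155633). In CeA bulk nuclei its promoter was at 39.1, 28.8 and 32.9 CPM in the KO libraries 1, 2 and 3 and at 35.6 and 37.4 CPM in the WT libraries 1 and 2. In cortex bulk nuclei it was at 26.0, 36.6 and 41.1 CPM in KO and at 33.3 and 45.8 CPM in WT. The difference averaged over regions was -0.27 ± 0.19 log2 (34.1 ± 5.89 CPM, n = 6, against 38.0 ± 5.45 CPM, n = 4, adjusted p = 1.00). The window around the start site lies outside any deleted part that is given, and the KO is in SOM+ cells alone, a part of the bulk nuclei, so these values check nothing about the deletion. In SOM+ nuclei, where the gene was intact, it was at 16.4 ± 0.751 CPM in CeA control, 21.7 ± 0.0972 in CeA fear, 24.4 ± 0.732 in cortex control and 27.2 ± 0.115 in cortex fear (n = 2 each). These rest on 59 to 350 counts per library, where counting error alone is larger than these SDs. The SDs therefore understate the spread, and Erbb4 was not called for fear conditioning.

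Averaged over regions, 6 KO against 4 WT libraries, Acadl, a mitochondrial enzyme of fatty acid oxidation on the chromosome of Erbb4, was at 21.1 ± 3.66 CPM in KO and 39.4 ± 2.94 CPM in WT (SD; -0.92 ± 0.19 log2, adjusted p = 1.00; chromosome 1, 66908884 to 66910883), each KO library below each WT library. Bzw1 was at 54.7 ± 5.54 against 84.0 ± 9.02 CPM (-0.70 ± 0.15), Myl1 differed by -1.04, and Reln, the extracellular matrix protein of interneurons, by -0.52. On the other side stood the transcription factor subunit Taf1b (1.33), the casein gene Csn2 (2.25) and Chd3os (0.58). None of these passed, with 0 of 25196 promoters called by edgeR, DESeq2 and limma with cyclic loess and 872 (3.46%) at an unadjusted p under 0.05 by edgeR. Clustered protocadherins were higher in KO as a list by camera (58 measured, median 0.42, adjusted p = 2.09e-08, and adjusted p = 0.795 with an estimated correlation), with Pcdhb1 at 1.41 and Pcdhga11 at 0.84 and 0 members called (0 adjusted over the list alone). Hox (median 0.34, adjusted p = 0.000389), ribosomal protein (0.11, adjusted p = 0.0200) and olfactory receptor promoters (0.17, but -0.03 under cyclic loess, adjusted p = 0.000871) were also higher as lists (adjusted p = 0.795 with an estimated correlation for each). ErbB and neuregulin signalling genes had 0 of 48 called (0 adjusted over the list alone, median 0.01), and the pallial factor Zbtb18 was the only member of any list to pass when adjusted over the list alone, in the fit with the labelled sex.

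That average carried limits of design. In both regions KO 2 held 0 Y-linked counts and WT 1 held some, so libraries of one number may come from the same mouse. The 6 KO and 4 WT libraries may then be fewer mice, which the fit does not take into account. Both bulk libraries labelled female were WT 1, so with the labelled sex as a term the KO difference rested on the WT 2 libraries, and without that term edgeR also called 0 in the fit by group means. Without the library labelled cortex KO 3, edgeR called 125 promoters, 10 higher and 115 lower in KO. Among them were Acadl, Bzw1, Myl1, Reln, Taf1b and Csn2. Cortex KO 3 and cortex WT 2 resembled each other (r = 0.973) and stood apart from the other bulk libraries. Leaving out KO 3 alone set the other cortex KO libraries against that WT 2, so these calls may follow this structure and not genotype. With the replicate number as a block, 3 were called, Ddx3y, Eif2s3y and Uty, chosen after their values were seen, all lower in KO. The libraries labelled KO 2 had 0 counts at these Y-linked promoters. Sst was at -0.42 ± 0.27 (15.0 ± 6.6 CPM, n = 6, against 18.3 ± 3.86 CPM, n = 4, adjusted p = 1.00).

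In CeA bulk nuclei alone, 3 KO against 2 WT libraries, the promoters named by rule were Zbtb18, a repressor of neuronal differentiation genes (1.10), Taf1b (1.58) and Zc3h10 (0.72) on one side and the muscle myosin light chain gene Myl1 (-1.42), Figf (-1.47) and Tnip3 (-1.29) on the other (adjusted p = 0.999 for each). The kinase gene Akt2, downstream of ErbB receptors, was at 0.80, Gad2 at 0.53 and Dlx6 at 0.46. GABAergic neuron (median 0.29, adjusted p = 0.0253), ribosomal protein (0.16, adjusted p = 0.00111), OXPHOS subunit (0.12, adjusted p = 0.0230) and clustered protocadherin promoters (0.40, adjusted p = 6.76e-05) were higher in KO as lists by camera (adjusted p = 0.662 with an estimated correlation for each), with 0 members called and 0 adjusted over each of these lists alone. Promoters called numbered 0 by edgeR, DESeq2 and limma with cyclic loess, with 745 (2.96%) at an unadjusted p under 0.05 by edgeR. The Y-linked Ddx3y, Eif2s3y and Uty, 3 in all, were called with the replicate number as a block. Erbb4 was at -0.23 ± 0.25 and Sst at -0.17 ± 0.34.

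In cortex bulk nuclei, 3 KO against 2 WT libraries, Acadl was at 21.3 ± 5.57 against 41.2 ± 3.61 CPM (SD; n = 3 and 2; -1.0 ± 0.24 log2, adjusted p = 0.945). Mcmdc2 was at -0.90 and Bzw1 at -0.72, while Treml1 (1.95), the interneuron factor Lhx6 (0.96) and Cga (1.86) had positive differences. The term for labelled sex, shared by both regions, moved the WT level by the gap between WT 1 and WT 2, and without it these differences were 0.52, 0.41 and 1.08. The growth factor receptor Egfr was at -0.65, Erbb4 at -0.32 ± 0.23 and Sst at -0.67 ± 0.34 (10.6 ± 3.09 against 15.7 ± 4.08 CPM). By edgeR, DESeq2 and limma with cyclic loess 0 promoters were called, with 823 (3.27%) at an unadjusted p under 0.05 by edgeR. Lhx6 was called when adjusted over the GABAergic list alone, but that rested on the sex term. This term draws on the gap between WT 1 and WT 2 in cortex (22.0 and 13.1 CPM) and in CeA (32.4 and 14.9 CPM). In cortex WT 1 lay within the KO libraries (25.2, 21.2 and 25.2 CPM). The female label of WT 1, on which the sex term rests, goes against the 683 Y-linked counts of that library in cortex. Without the library labelled cortex KO 3, edgeR called 985, of which 105 were higher and 880 lower in KO. Among them were Acadl, Mcmdc2, Bzw1, Treml1, Lhx6 and Cga. Cortex KO 3 and cortex WT 2 stood apart from the other bulk libraries on the first principal component (scores of -71.3 and -62.8). Without KO 3, the KO libraries left were set against that WT 2, so these calls may follow this structure and not genotype. With the replicate number as a block edgeR called 3, Ddx3y, Eif2s3y and Uty, named after their values were seen. By camera, Hox (median 0.55, adjusted p = 8.22e-07), clustered protocadherin (0.46, adjusted p = 1.55e-06) and olfactory receptor promoters (0.30, but -0.09 under cyclic loess, adjusted p = 1.55e-06) were higher in KO. Receptors for GABA and neuropeptides were lower (-0.23, adjusted p = 0.0074, and adjusted p = 0.725 with an estimated correlation for each). Scaling by total count moved the median of all promoters from 0.02 to 0.13 here.

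The KO difference was also compared between the regions. Klhl5 (0.94), Utp6 (0.98) and Pdk3 (0.86) were named by rule with positive differences of CeA minus cortex effect, and elastin Eln (-1.72), the stress kinase gene Mapk8 (-1.83) and Srms (-1.67) with negative ones (adjusted p = 0.968 for each). By edgeR, DESeq2 and limma with cyclic loess 0 promoters were called, and 590 (2.34%) had an unadjusted p under 0.05 by edgeR. As lists, ribosomal protein (median 0.16, -0.01 under cyclic loess, adjusted p = 0.0476) and OXPHOS subunit promoters (0.18, adjusted p = 0.0149) were higher by camera and Hox (-0.43, adjusted p = 0.0047) and olfactory receptor promoters (-0.25, 0.14 under cyclic loess, adjusted p = 0.00609) lower. Camera with an estimated correlation gave adjusted p = 0.647 for OXPHOS subunits and 0.752 for the others. Without the library labelled cortex KO 3, Asxl3 and P2ry1 were called, chosen after their values were seen. Cortex WT 2, which resembles KO 3, stayed in that fit, so these calls carry the same limit. Scaling by total count moved the median of all promoters from 0.01 to -0.14. Across 16359 promoters, which are not independent replicates, the KO differences of the regions correlated at r = 0.0636 without the sex term.

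**Figure D4:**
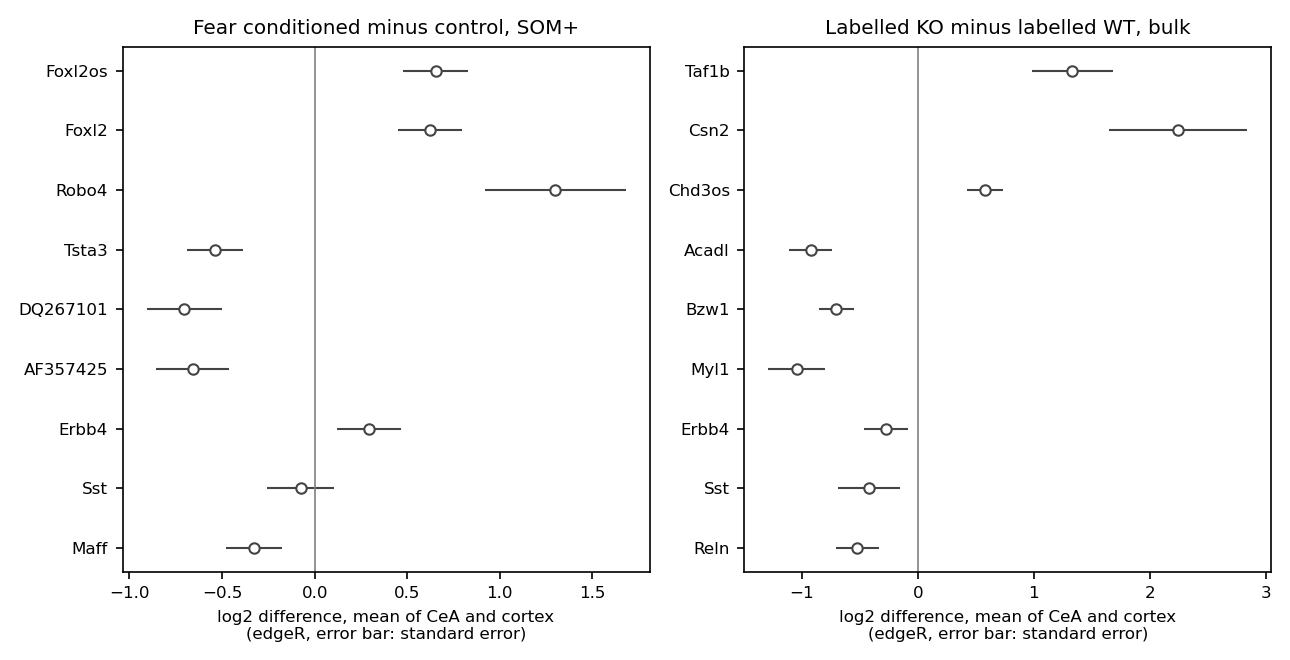
Log2 differences of 9 promoters each for fear conditioning and for Erbb4 KO, both averaged over regions, with SE bars from edgeR; open points were not called. All the points were open, among them Acadl at -0.92.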

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

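All tests in this part were chosen after the results they bear on were seen.

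The bulk libraries labelled WT 1 drew attention because they are labelled female and yet held counts at Y-linked promoters, 285 in CeA and 683 in cortex (55.4 and 112 CPM of the library total without TMM scaling), with Xist at 16.8 and 5.58 CPM (TMM-scaled). The libraries labelled KO 2, labelled male, held 0 Y-linked counts in both regions and had Xist at 24.3 and 25.5 CPM. The remaining 6 bulk libraries had 67.6 to 114 CPM at Y-linked promoters, again without TMM scaling, and Xist at 4.46 to 11.3 CPM. CeA WT 1 was the least clear, as it lay below these 6 at Y-linked promoters and between them and KO 2 in Xist. Wrong sex entries beside right genotypes and an exchange of KO 2 and WT 1 between the genotypes cannot be told apart by these counts, since 4 of the 10 bulk libraries go against the labelled sex as labelled and 0 would after the exchange. With the exchange, 1 promoter within 10 Mb of Erbb4 separated the genotypes at an unadjusted p under 0.01, against 4 as labelled and up to 15 in another of the 10 splits, one that called 490 promoters over the genome and so follows another structure of the samples. The share near Erbb4 was 0.565% with the exchange (0.115% over all promoters) and 2.26% as labelled (0.468% over all promoters). Fewer promoters separated everywhere with the exchange, so 1 against 4 does not favour the labels. Acadl (21.6 and 17.8 CPM in KO 2 of CeA and cortex, 38.3 and 38.6 in WT 1) and Bzw1 (54.7 and 58.2 against 82.8 and 73.5 CPM) go with the genotype labels as given, but they were picked for separating those labels, so both readings stay open, and no biological explanation was tested.

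The difference between CeA and cortex was itself different in SOM+ and in bulk nuclei at 10470 of 25246 promoters by edgeR (10014 under cyclic loess). As a signed value of CeA minus cortex, it was more positive in SOM+ nuclei at 4451 and more positive in bulk nuclei at 6019. These counts do not tell in which nuclei the difference was greater in size. Enrichment was lower in CeA than in cortex among SOM+ nuclei and, not detectably, higher in CeA among bulk nuclei. It may therefore account for part of these counts. The neuropeptide Y receptor gene Npy1r differed by 0.75 log2 between CeA and cortex in SOM+ nuclei and by -0.72 in bulk nuclei (adjusted p = 3.04e-06 for the difference), values that stayed opposite under cyclic loess at 0.88 and -0.66. The cortical factor Cux1 differed by -1.12 in SOM+ and 0.46 in bulk nuclei (adjusted p = 5.53e-08), and by -0.83 and 0.46 under cyclic loess. The bulk call of Cux1 ended without any 1 of CeA KO 2, CeA KO 3, CeA WT 1, CeA WT 2, cortex KO 2, cortex WT 1 and cortex WT 2 (adjusted p up to 0.322). Both genes were chosen after their values were seen.

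Promoter enrichment differed between the groups of the largest comparisons, so it may account for part of their calls. Among promoters of at least 10 CPM this was argued against as the whole cause, since 79.2% of the 9528 calls between CeA and cortex in SOM+ nuclei and 84.8% of the 11528 calls between SOM+ and bulk nuclei were made with the same sign under cyclic loess, which removes a trend with level. On the side that enrichment would give, fewer were kept: 71.6% of 6573 lower in CeA SOM+ nuclei and 77.4% of 7360 higher in SOM+ than in bulk nuclei. On the opposite side 96.1% and 97.8% were kept. Enrichment may therefore account for part of the calls at these promoters too. Among promoters under 10 CPM, 24.0% of the 2359 called higher in CeA SOM+ nuclei and 36.9% of the 3551 called lower in SOM+ than in bulk nuclei were made again, as a difference in enrichment would give. Of the biological differences of the design, region remains open and untested for the kept calls of the first comparison, and cell type for those of the second, where sort, mouse line and preparation differ with it.

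Other splits of the same libraries, refitted with the remaining factors as additive terms, tested whether grouping by chance could give as many calls. A split that coincides with such a factor was left out, among them the split by region for fear conditioning, which called 12943 without the region term. For SOM+ against bulk nuclei the real split called 12485 promoters and the highest of the others 0, so that 1 of 34 splits reached the real count, the smallest share possible. For CeA against cortex the real split called 12693 in SOM+ nuclei and the highest other 2 (1 of 34). In bulk nuclei it called 4170 and the highest other 2741 (1 of the 60 splits run, of 126 possible). The other splits mix the compared groups on each side, which widens the spread and lowers their counts. They therefore do not exclude chance for these comparisons. For Erbb4 KO, the real split called 1 promoter, Acadl, in this additive fit without the sex term, and 8 of the 60 splits run, of 210 possible, called as many. The highest of these called 4852, which points to a structure of the bulk samples other than genotype: it set CeA KO 1, CeA KO 3, cortex KO 3 and cortex WT 2 against the rest. For fear conditioning, the real split called 0, a count that all 34 of the splits reach whatever the data, so this says nothing about chance. The highest called 536, a split by library number and so by labelled sex, which again points to a structure of the samples. Nor is chance excluded for Erbb4 KO.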

How the results depend on the processing

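The choices of tool, scaling, filter, chromosomes, left-out library, block, sex term, list correlation and enrichment ratio were made before the data were examined; sex as the Y-linked promoters show it, fits without named bulk libraries and the 10 CPM minimum were chosen after. Calls were 0 for fear conditioning and Erbb4 KO with DESeq2, total count scaling, cyclic loess, no filter and autosomal promoters, and for KO also with no sex term and with Y-shown sex, all fitted by group means. Leaving out each library in turn gave 0 to 4 calls for fear conditioning in CeA, 0 to 3 in cortex, 0 to 3 averaged and 0 to 3 for its interaction, and 0 to 0 for KO in CeA, 0 to 985 in cortex, 0 to 125 averaged and 0 to 2 for its interaction. It gave 9858 to 12779 between the regions in SOM+ nuclei, 889 to 6991 in bulk nuclei and 13310 to 14500 between SOM+ and bulk nuclei. A lone library left in a group was assumed to vary like the other groups. With the replicate number as a block, KO calls were 3 in CeA, 3 in cortex and 3 averaged, all Y linked, which the 0 Y-linked counts of KO 2 give by construction. Calls between bulk regions were 645 without KO 2 and WT 1 (0 for KO in its 4 comparisons) and 1974 without cortex KO 3 and WT 2, with fewer samples. Lists passing camera fell to 0 with an estimated correlation in cortex after fear conditioning, in the 4 KO comparisons, between the regions in SOM+ and in bulk nuclei and between SOM+ and bulk nuclei, from 2, 4, 4, 4, 4, 8, 7 and 16. The enrichment was 48.4 in cortex SOM+ fear, 15.2 in cortex bulk KO and 15.1 in cortex bulk WT as a ratio of means.

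Of 117 named promoters with a call, 107 kept it without each library in turn and 10 lost it; of 82 without, 14 gained one. Signs turned for Sst in the fear interaction (-0.036 under cyclic loess, -0.007 with the block), Sst for KO in CeA (0.021 with Y-shown sex), Erbb4 in the KO interaction (-0.053 with total count), Erbb4 between bulk regions (0.055 with total count), Sst between SOM+ and bulk (-0.17 with total count, -0.079 under cyclic loess) and Eif2s3y there (0.30 under cyclic loess, 0.37 with Y-shown sex); the cause was not tested. Of 12143, 4253 and 15437 calls for region in SOM+, region in bulk and SOM+ against bulk, 8353, 3663 and 11441 were made with the same sign under cyclic loess. With 2 or 3 libraries per group, changes of 1.5-fold were missed at most of the promoters changed in simulated data, so a count of 0 does not show that no promoter changed.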

Other observations

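All tests in this part were chosen after the results they bear on were seen.

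The sexes of the SOM+ libraries differed at promoters of the sex chromosomes and of autosomes. Xist, the RNA that silences an X chromosome, was higher in the 4 libraries labelled female by 1.25 ± 0.20 log2 (18.0 against 7.78 CPM; adjusted p = 1.21e-06), and the Y-linked Uty, Eif2s3y and Ddx3y had 0 CPM in them against 50.2, 36.8 and 31.9 CPM in the 4 labelled male. Genes that escape X inactivation were higher in females: the RNA helicase Ddx3x by 0.83 ± 0.13 (92.2 against 50.9 CPM; adjusted p = 1.72e-06), the histone demethylases Kdm5c by 0.70 ± 0.13 (90.1 against 55.5 CPM; adjusted p = 0.000184) and Kdm6a by 0.63 ± 0.15 (153 against 99.0 CPM; adjusted p = 0.00976). Of 25157 promoters 188 were called by edgeR, 28 higher and 160 lower in females, and X- or Y-linked promoters made up 11.7% of the calls and 3.93% of those tested (Fisher's exact p = 5.11e-06). Of the calls, 166 were autosomal, 12.7% of them higher in females, including Nrip1 (-0.81), the calcium channel subunit Cacna2d1 (-0.80) and Casd1 (-0.79). Under cyclic loess 1282 were called, 1247 of them autosomal. Sex and library number coincide in these libraries, so for autosomal promoters a part of sex and a part of preparation cannot be separated.

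Most windows of the imprinted Dlk1-Dio3 domain, a cluster of small RNA genes on chromosome 12 (110690033 to 111518439), were lower after fear conditioning. Without the 4 windows that raised the question, 71 of 74 windows were lower after fear conditioning averaged over regions, 55 in CeA and 72 in cortex, with an edgeR median of -0.25 log2 (-0.17 in CeA and -0.30 in cortex, -0.23 under cyclic loess). The median over these windows on the scale used for the splits was -0.24, as low in 1 of 68 signed splits of the 8 SOM+ libraries, with -0.23 the lowest of the others. The domain was picked from these same fear and control labels, and the windows kept are neighbours of those left out. A low rank was therefore likely from the start, and it does not decide whether fear conditioning acts on the domain. For a difference in enrichment, 0% of 10000 lists of promoters matched on CPM had a median as low (the middle one was at 0.03). The domain was picked for low values under these labels, so this share too was likely from the start. It does not decide whether enrichment lowered these windows. Those lists hold scattered promoters, which vary together less than neighbours do, so the 0% overstates how rare such a median is. Of the cluster's windows 0 were called and 11 had an unadjusted p under 0.05; neighbouring windows share regulation and in part reads, so they are not independent, and reads shared between the repeated small RNA genes were not tested.

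A haplotype carried along with the targeted allele could set the KO libraries apart near Erbb4. Acadl, 2.2 Mb from Erbb4, was called in a fit with genotype and region as additive terms and no sex term (-0.89 log2; adjusted p = 0.0434), though not in the fit by group means without the sex term, at 17.8 to 27.7 CPM in the 6 KO libraries and 37.1 to 43.7 CPM in the 4 WT libraries. Within 10 Mb of Erbb4, 4 of 177 promoters had an unadjusted p under 0.01 (2.26%, against 0.484% over the autosomes), the others being Myl1 (-0.72), Cyp27a1 (-0.63) and Icos (0.86), all chosen after their values were seen. Without Acadl, Bzw1 and Myl1, which raised the question, 2 of 175 remained (1.14%), and the region ranked 20 of 131 beside tiles of the autosomes outside it, against 5 with them. The highest share among the tiles was also on chromosome 1, from 80000001 on (3.03% of 198 promoters), followed by the next tile from 100000001 on (2.94% of 34) beside 1 on chromosome 12 (2.94% of 102), and 5 of the 20 smallest p were on chromosome 1. Other splits of the bulk libraries by number gave 15, 7 and 5 such promoters near Erbb4, with higher shares over all promoters (7.76%, 4.35% and 1.42% against 0.468% as labelled). The rest gave 0 to 3, and the split of KO 1, WT 1 and WT 2 gave 3 (1.69%, against 0.163% over all promoters). The count near Erbb4 is thus not particular to genotype. The rank without the promoters seen first does not set the region apart from the ordinary spread of tiles, so a carried haplotype stays open.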
